A study of Mus musculus with 14 samples.

How the data were processed

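RNA was measured in whole hearts of untreated male C57BL/6 mice. The series holds 14 libraries, each a column of the count table: 3 wild-type and 3 knockout hearts at 2 months of age, and 4 wild-type and 4 knockout hearts at 15 months. In the knockout, Sqstm1 (which encodes p62) is flanked by loxP sites and removed by Cre recombinase under the Myh6 promoter, which is active in cardiac muscle cells. The libraries were made from total RNA with a stranded kit that depletes ribosomal RNA, per the labels' protocols. The labels give every library its genotype, age and replicate number. They do not say whether equal numbers share a litter, a day or a batch, or that the hearts of a group were handled separately, so the p-values measure the spread between these samples.

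The authors deposited raw counts, whole numbers of reads per gene for 55487 Ensembl gene identifiers. The tools named are cutadapt 1.16, STAR 2.7.3a, featureCounts 1.6.3 and DESeq2 1.26.0, with the mouse build GRCm38, per the submitters' processing notes. The annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Reads of overlapping genes on opposite strands, and of near-identical gene copies, could therefore have been shared or lost before the deposited counts were made. Gene symbols, positions and exon lengths were taken from GENCODE M21 on GRCm38, which held 55227 of the identifiers. All coordinates are from that annotation. The count table held 0 columns without a sample.

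Total counts ranged from 20218992 to 30404416 per library. Between 27.5% and 46.0% of these counts fell on mitochondrially encoded genes, and the 10 most counted genes of a library took 31.4% to 47.9%. The counts were compared between all pairs of libraries with a chi-square statistic. The lowest value was 30.2 per degree of freedom within a group and 19.8 over all pairs, so no library was a repeat of another within sampling noise. Counting intervals cover counting error only, since the reads carry no molecular identifiers.

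Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the 4 groups (minimum count 10, minimum total 15), which left 15528 genes. Libraries were scaled with TMM. A quasi-likelihood model with robust moderation and 1 mean per group was fitted to all 14 libraries, and the quasi-likelihood F-test was applied to 6 contrasts: knockout against wild type at 2 months, at 15 months and averaged over both ages, 15 against 2 months within each genotype, and the difference between the knockout effects at the 2 ages. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05 and no fold minimum. The standard error (SE) of a log2 fold change is its size divided by the square root of the F statistic. Levels are CPM, counts relative to the TMM-scaled library total, given as mean ± SD. Sqstm1 was also compared with an exact two-sided permutation test on the mean of log2 CPM.

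The comparisons, the tests, the alternatives, the gene lists and the rule for naming genes were fixed before the data were examined. The 34 gene lists of pathways, organelles and cell types came from textbook knowledge. They have 829 entries for 806 distinct genes, of which 53 entries were not tested for low counts. Each list was tested with camera in limma 3.58.1 with a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast by the Benjamini-Hochberg method. An estimated correlation and fry, which asks whether a list's genes move on balance in 1 direction, were alternatives. Members were also counted after adjustment over the list alone.

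The rule named Sqstm1, then the 8 largest rises and the 8 largest falls among genes past the threshold with a mean CPM of at least 1 and no overlap between the groups compared. From these were excluded predicted models, clones, ribosomal proteins, histones, and small RNAs and pseudogenes recognised by symbol or annotated biotype. The use of the biotype was added after the data were seen, and changed only the picks with age in knockout hearts, where it took out mt-Tl2, Rny1 and Rny3 and let in Ighg2c, Kcne1 and Tmem35a. The rule further named up to 4 members per list past the threshold, or as values up to 2 members with the smallest p where no member passed, and 12 fixed genes in every contrast. Of the genes the rule named, 1 is not reported here.

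Alternatives were size factors by the RLE method, no filter, a filter at a mean CPM of 1, DESeq2 1.42.0, limma voom, a fit of only the groups compared, a replicate block, leaving out mitochondrially encoded genes, leaving out each library in turn, an adjusted p threshold of 0.1, and a minimum log2 fold change of 1. After the data were seen, 3 covariates were added: the length slope of a library, its atrial score, and 2 surrogate variables from sva 3.50.0. The length slope is the regression of a library's log2 CPM, relative to the mean over libraries, on log2 exon length of protein-coding genes. It differed between the ages, so as a covariate it also takes up part of an age difference. The atrial score is the mean log2 CPM of Myl4, Myl7 and Sln. A clock score, the mean log2 CPM of Dbp, Ciart, Tef and Per3 relative to the mean over libraries, was computed for description. Principal components used the 2000 most variable genes.

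The edgeR and camera steps were tested on simulated counts with known changes, drawn with the real means and library sizes. At a 2-fold change the quasi-likelihood test recovered 38.8% of 67 seeded genes in the simulated comparison of genotypes at 2 months (15283 genes tested), 53.7% at 15 months (15296 genes) and 76.1% for the mean over both ages (15304 genes). At 2-fold it recovered 44.8% of 67 genes for age in wild type (15300 genes), 61.2% for age in knockout (15301 genes) and 13.4% for the difference of knockout effects (15306 genes). At 4-fold, with 66 seeded genes, the shares were 87.9%, 97.0%, 100%, 92.4%, 90.9% and 74.2% in the same order, and at 1.5-fold 2.99%, 13.4%, 29.9%, 5.97%, 4.48% and 1.49%. False calls numbered 0 to 4 per comparison. The simulated counts were drawn for each gene independently, without shared differences between libraries such as atrial transcripts, so these rates need not hold for the real libraries. A seeded list shift of −0.2 was called by camera in 4 of these 6 simulated comparisons, with adjusted p = 0.139 at 2 months and 0.184 for the difference.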

Results

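Transcript levels were compared in whole hearts of male mice with and without Sqstm1 in cardiac muscle. Sqstm1 encodes p62, an autophagy receptor that binds Keap1, the protein that holds the transcription factor Nrf2 at low levels. The series title names Nrf2 protein and oxidative stress as the subject, so the genotypes were compared at each age with attention to Nrf2 target genes, and the ages were compared within each genotype. Young hearts were taken at 2 months (3 wild type, 3 knockout) and aged hearts at 15 months (4 wild type, 4 knockout). Total counts per library were 20218992 to 23651521 in wild type and 21969498 to 26230284 in knockout at 2 months, and 22362567 to 29979173 in wild type and 21526968 to 30404416 in knockout at 15 months.

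The libraries differed in several ways besides genotype and age. Wild-type replicate 1 at 2 months held atrial transcripts, with Myl7 at 638 CPM, Myl4 at 485 CPM and Sln at 144 CPM, whereas Myl7 was between 0.0597 and 0.303 CPM in the other 2-month libraries. At 15 months Myl7 reached 58.1 CPM in knockout replicate 1, 39.7 CPM in wild-type replicate 1, 26.9 CPM in wild-type replicate 4 and 15.0 CPM in wild-type replicate 2, and was below 1 CPM in the other 15-month libraries. The length slope was negative in all 6 libraries at 2 months, between −0.180 and −0.016, and positive in 6 of 8 at 15 months, with −0.067 in both exceptions, wild-type replicate 2 and knockout replicate 1. Knockout replicate 1 at 15 months also had the highest mitochondrial share, 46.0%. The clock transcript Ciart was at 20.2 and 16.3 CPM in the wild-type and knockout replicate 3 at 2 months, between 0.657 and 1.20 CPM in the other 2-month libraries, and between 7.07 and 13.6 CPM at 15 months. The first principal component took 36.2% of the variance of the 2000 most variable genes and the second 13.5%.

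**Figure D1:**
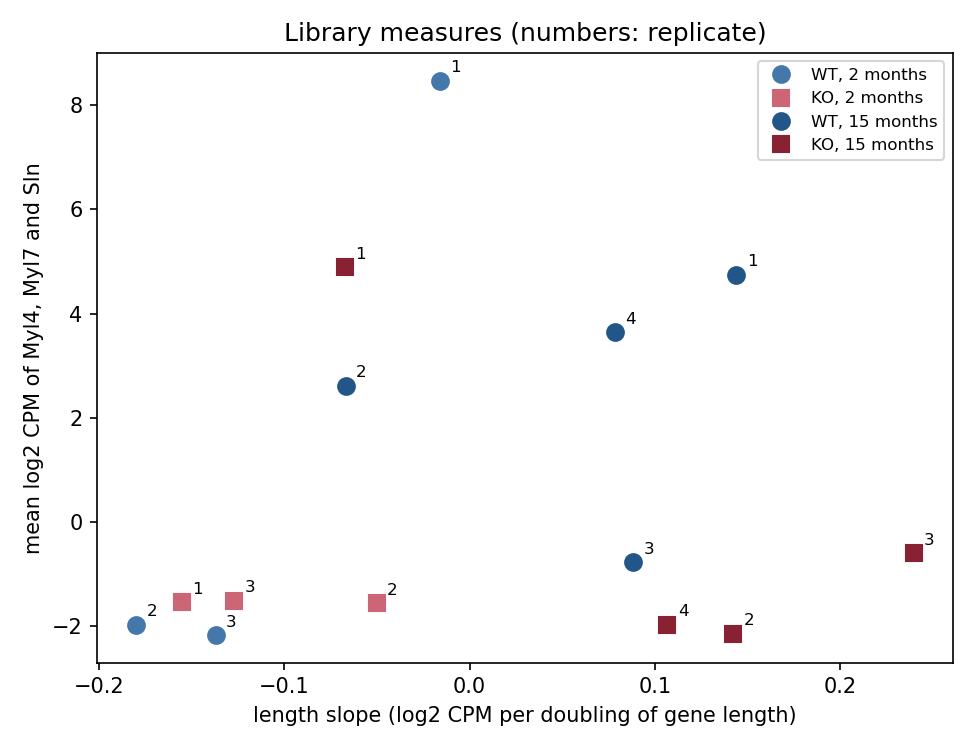
Length slope of each library (x axis, log2 CPM per doubling of gene length) against its atrial score (y axis, mean log2 CPM of Myl4, Myl7 and Sln), 1 point per library, numbered by replicate. Wild-type replicate 1 at 2 months has the highest atrial score, 8.47, and the 2-month libraries lie at negative length slopes.

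Sqstm1 (ENSMUSG00000015837, chromosome 11, 50199366 to 50210827, minus strand, GRCm38) was lower in every knockout library than in any wild-type library. At 2 months it was at 177, 139 and 169.5 CPM in wild type and at 15.2, 14.7 and 19.2 CPM in knockout, means of 161.7 ± 20.03 and 16.4 ± 2.49 CPM (SD, n = 3 each). At 15 months it was at 208, 186, 238 and 173 CPM in wild type and at 14.6, 37.0, 16.2 and 17.6 CPM in knockout, means of 201 ± 28.3 and 21.3 ± 10.5 CPM (SD, n = 4 each). The knockout mean was 10.1% of wild type at 2 months and 10.6% at 15 months. The log2 fold change was −3.30 (SE 0.31, edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 0.00036) at 2 months and −3.23 (SE 0.26, edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 6.46e-05) at 15 months. An exact two-sided permutation test gave p = 0.1 for 3 against 3 hearts and p = 0.0286 for 4 against 4, the smallest values these designs allow. Counts of the whole gene include exons that the deletion may leave and cells in which Myh6 is silent.

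**Figure D2:**
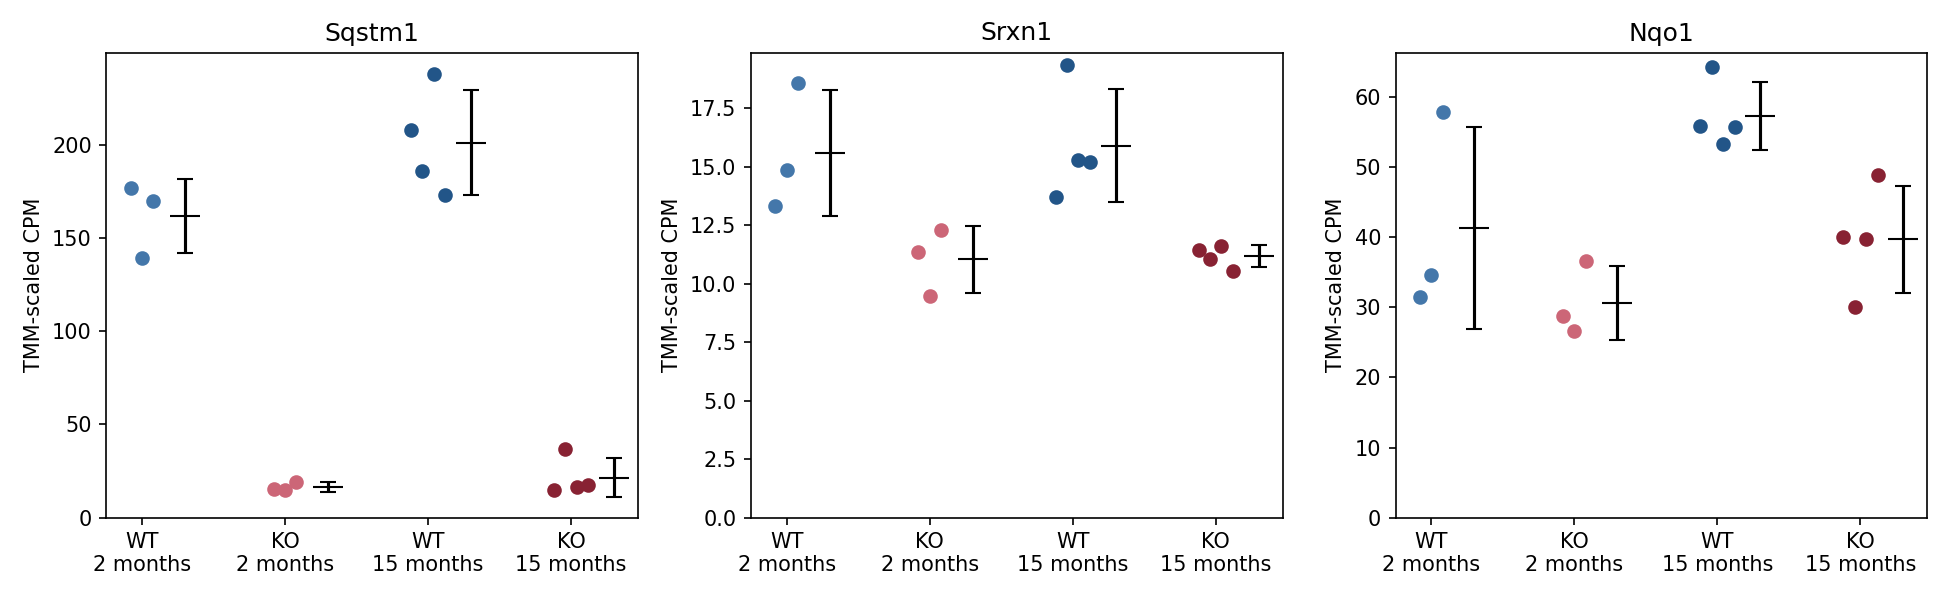
TMM-scaled CPM of Sqstm1, Srxn1 and Nqo1 (y axes) by genotype and age (x axis), with 1 point per heart and the group mean and SD. Knockout hearts lie at 14.6 to 37.0 CPM for Sqstm1 against 139 to 238 CPM in wild type, and at 9.49 to 12.3 CPM for Srxn1 against 13.3 to 19.4 CPM.

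At 2 months Sqstm1 was the only gene of 15528 to pass the test between genotypes, and it fell. Nrf2 itself is encoded by Nfe2l2, whose transcript gave a log2 fold change of 0.15 (SE 0.27), and Keap1 gave 0.11 (SE 0.14). Among Nrf2 target genes, the quinone reductase Nqo1 was at 30.7 ± 5.29 CPM in knockout and 41.3 ± 14.4 CPM in wild type (SD, n = 3 each; log2 fold change −0.43, SE 0.22), and Srxn1, which reduces oxidised peroxiredoxins, was at 11.05 ± 1.43 against 15.6 ± 2.7004 CPM (SD, n = 3 each; −0.50, SE 0.16). Hmox1 gave −0.54, Gclc −0.26, Gclm 0.02 and Txnrd1 −0.12. The natriuretic peptide genes Nppa and Nppb gave −0.55 and −0.27, the fetal myosin Myh7 0.52, and the autophagy genes Nbr1 and Map1lc3b 0.30 and −0.06. Besides Sqstm1 none of these genes passed (lowest adjusted p = 0.9997, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). The signs of Nfe2l2, Gclm, Nppa, Nppb and Map1lc3b turned in other settings.

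The Nrf2 target list had 33 measured members, of which 20 lay below 0 at 2 months, with a median log2 fold change of −0.13, and 0 passed over all genes or adjusted over the list alone. Camera with Benjamini-Hochberg adjustment called the list lower (adjusted p = 0.00281), and the adjusted p was 0.196 with an estimated correlation. The call ended without wild-type replicate 1 (adjusted p = 0.0656), wild-type replicate 3 (0.117) or knockout replicate 2 (0.0701). The sarcomere list lay higher, with 19 of 20 members above 0 and a median of 0.24 (camera adjusted p = 1.06e-05; adjusted p = 0.196 with an estimated correlation), and so did fatty acid oxidation, with a median of 0.13 (0.0121; 0.755 with an estimated correlation).

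Lists of connective tissue and immune cells lay lower in knockout hearts at 2 months. In the extracellular matrix list 37 of 38 members were below 0, with a median of −0.66, and Thbs4 at −1.41 (SE 0.42) and Col12a1 at −2.91 (SE 0.94), 0 passing over all genes or adjusted over the list alone. Camera with Benjamini-Hochberg adjustment gave adjusted p = 8.77e-13 for this list, 3.55e-09 for fibroblast markers (18 of 18 below 0, median −0.54), 9.01e-07 for inflammation (median −0.65, Cxcl1 at −1.44), 1.82e-07 for macrophage markers (21 of 21 below 0, median −0.32), 0.00281 for immediate early genes (median −0.39) and 0.00299 for atrial markers (median −0.47). With an estimated correlation these adjusted p-values were 0.467, 0.424, 0.424, 0.233, 0.725 and 0.725. All of these lists except macrophage markers lost their call without wild-type replicate 1, the library with atrial transcripts, whose Fos level was 30.2 CPM and whose extracellular matrix genes lay 1.92 log2 units above the mean of all genes, against 0.388 and 0.498 in the other wild-type libraries. Without it Thbs4 was at −0.69, Col12a1 at −0.81 and Cxcl1 at −0.80, and the camera adjusted p was 0.163 for extracellular matrix, 0.163 for fibroblasts, 0.216 for inflammation, 0.841 for immediate early genes, 0.163 for fatty acid oxidation and 0.401, with the opposite direction, for atrial markers, and 2 lists were called in place of 9, macrophage markers and the sarcomere (adjusted p = 0.0016 for both), whereas 17 were called without wild-type replicate 2. Immediate early genes also lost the call without wild-type replicate 3 (0.253), knockout replicate 1 (0.0901) or knockout replicate 2 (0.219), and fatty acid oxidation without knockout replicate 2 (0.0899).

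Single members of other lists passed at 2 months only when adjusted over the list alone. Mgat4b, whose annotated start at chromosome 11, 50210890 lies next to Sqstm1 on the opposite strand, gave 0.72 (SE 0.16) and was at 79.8 to 82.5 CPM in knockout against 41.8 to 60.0 CPM in wild type, 1 of 19 measured neighbours of Sqstm1 to pass. In the senescence and p53 list 2 of 21 measured members were higher, the p53 targets Eda2r and Phlda3 at 0.80 and 0.69, and 1 was lower. Also passing in this way were the smooth muscle gene Cnn1 at −2.64 (−1.16 without wild-type replicate 1) and the lipid droplet gene Cidea at 0.65. Among neighbours, Gfpt2 gave −1.05 without passing. Other tools and settings called 1 to 4 further genes, among them Epn3, which was chosen here after its values were seen (log2 fold change 1.08, SE 0.16, edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 0.0667). At an unadjusted p below 0.05 there were 494 genes, where 776.4 are expected by chance.

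At 15 months Sqstm1 was again the only gene to pass between genotypes by the edgeR quasi-likelihood test. DESeq2 called 6 genes, a fit of only the groups compared 2, and the fit without knockout replicate 1 called 3, with Sqstm1 in each. Srxn1 was at 11.2 ± 0.468 CPM in knockout and 15.9 ± 2.43 CPM in wild type (SD, n = 4 each; log2 fold change −0.51, SE 0.14), and Nqo1 at 39.7 ± 7.70 against 57.3 ± 4.84 CPM (SD, n = 4 each; −0.53, SE 0.19), with no overlap between the groups for either gene. Nfe2l2 gave 0.48 (SE 0.23), Keap1 −0.15, Hmox1 0.52, Gclc 0.03, Gclm 0.23 and Txnrd1 −0.33. Nppa gave −1.49 (SE 1.002), Nppb −1.15, Myh7 0.19, Nbr1 0.22 and Map1lc3b −0.15. Besides Sqstm1 none of these genes passed (lowest adjusted p = 0.999, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), and the signs of Gclc, Nppa, Myh7 and Map1lc3b turned in other settings. At an unadjusted p below 0.05 there were 616 genes.

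In the Nrf2 target list 20 of 33 members lay below 0 at 15 months, with a median of −0.08. No member passed over all genes, and 3 were lower adjusted over the list alone: Srxn1, and the glutathione S-transferases Gsta1 and Gsta2 at −1.87 and −2.32. Gsta1 and Gsta2 are similar copies at low levels (92 and 17 counts of Gsta2 over the wild-type and knockout libraries), so reads could be shared between them. Camera with Benjamini-Hochberg adjustment called the list lower (adjusted p = 0.00408), the adjusted p was 0.212 with an estimated correlation, and the call ended without knockout replicate 1 (adjusted p = 0.115), the library with the highest mitochondrial share.

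The connective tissue lists lay on the other side of 0 at 15 months. Extracellular matrix had 32 of 38 members above 0 and a median of 0.56 (camera with Benjamini-Hochberg adjustment, adjusted p = 1.12e-06), fibroblast markers 18 of 18 above 0 and 0.39 (1.12e-06), with Mfap5 at 0.56 (SE 0.16), and endothelial markers 0.46 (1.33e-05). With an estimated correlation these adjusted p-values were 0.761, 0.520 and 0.476. Without knockout replicate 3, which has the highest length slope (0.239) and an extracellular matrix level of 1.66, the camera adjusted p was 0.0841 for extracellular matrix and 0.135 for endothelial markers, and 6 lists were called in place of 10. Cell cycle genes had a median of 0.37, with Top2a at 1.09 (SE 0.32) and Mki67 at 0.95 (SE 0.30), a camera adjusted p of 4.13e-07 and 0.212 with an estimated correlation. Mitochondrially encoded mRNAs had a median of 0.45, with mt-Nd3 at 0.56 (camera adjusted p = 0.000435, 0.575 with an estimated correlation, and 0.230 without knockout replicate 1). Lower medians were found for cardiac stress genes (−0.23, camera adjusted p = 0.00408, 0.436 with an estimated correlation, 0.187 without wild-type replicate 1), the proteasome (−0.14, 0.00305, 0.763 with an estimated correlation, 0.162 without wild-type replicate 2 and 0.228 without knockout replicate 3), and nuclear-encoded oxidative phosphorylation (−0.12, 0.0127, 0.763 with an estimated correlation). The last call ended without wild-type replicate 2 (0.441), knockout replicate 2 (0.135) or knockout replicate 3 (0.802). With the length slope as a covariate, added after the data were seen, the camera adjusted p was 0.0974 for the proteasome and 0.415 for oxidative phosphorylation. The list of skeletal muscle, lung, thymus and liver markers held 3 measured genes with a median of −0.87 (camera adjusted p = 0.00408, 0.212 with an estimated correlation, 0.0602 without knockout replicate 1), and 1 was lower adjusted over the list alone. These were the muscle genes Mylpf, Acta1 and Ckm, so the list says nothing on lung, thymus or liver, and Acta1 is also in the cardiac stress list.

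Averaged over both ages, Sqstm1 was lower by a log2 fold change of −3.27 (SE 0.20, edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 1.61e-06) and no other gene of 15528 passed. At an unadjusted p below 0.05 there were 506 genes. Srxn1 (chromosome 2, 152105516 to 152111376) lay lower in each of 7 knockout hearts (9.49 to 12.3 CPM) than in each of 7 wild-type hearts (13.3 to 19.4 CPM), with a log2 fold change of −0.50 (SE 0.11, unadjusted p = 0.000345, adjusted p = 0.999 over all genes by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Nqo1 gave −0.48 (SE 0.15), Nfe2l2 0.31, Keap1 −0.02, Hmox1 −0.01, Gclc −0.11, Gclm 0.13, Txnrd1 −0.22, Nppa −1.02, Nppb −0.71, Myh7 0.35, Nbr1 0.26 and Map1lc3b −0.11, none of which passed, and the signs of Keap1, Hmox1, Gclm and Nppa turned in other settings. In the Nrf2 target list 23 of 33 members lay below 0, with a median of −0.12, and 2 were lower adjusted over the list alone, Srxn1 and Gsta1 (−1.89, SE 0.48; −1.24 without wild-type replicate 3 at 2 months). Camera with Benjamini-Hochberg adjustment called this list lower (adjusted p = 0.000165), with an adjusted p of 0.0724 with an estimated correlation and 0.0776 by fry, and the call held without any 1 library. Relative to the mean of all genes, the list mean was 1.44 to 1.58 log2 units in wild-type and 1.24 to 1.40 in knockout libraries at 15 months, and 1.08 to 1.31 and 0.988 to 1.12 at 2 months.

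**Figure D3:**
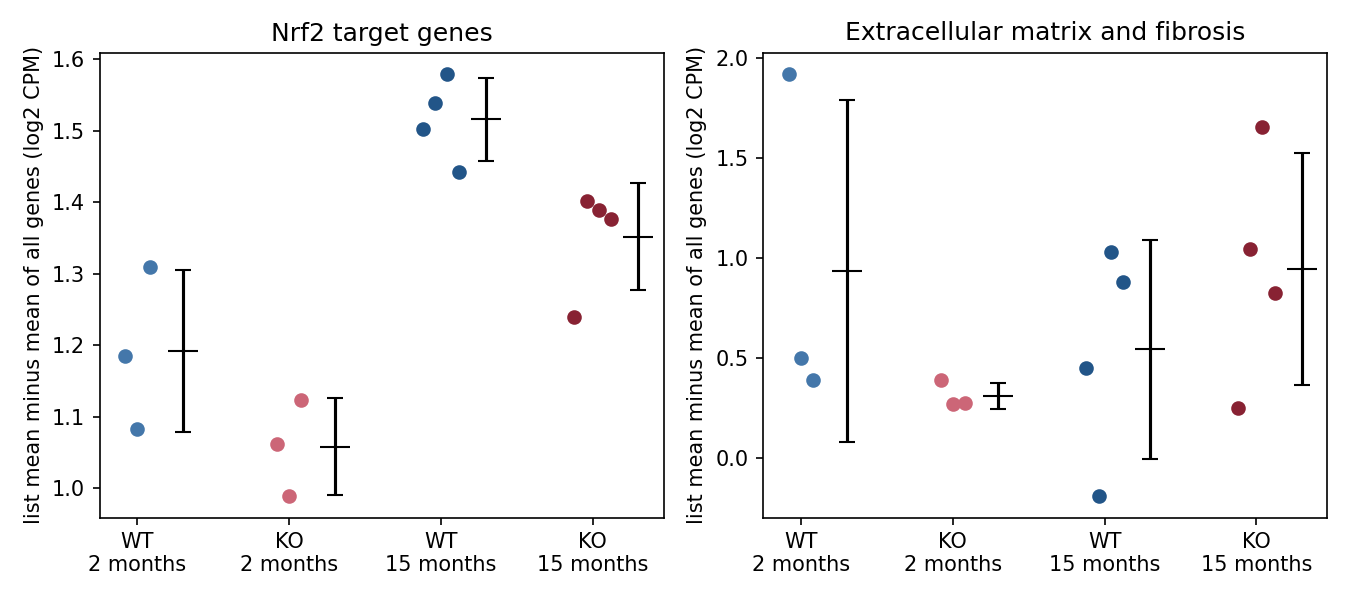
Mean log2 CPM of the Nrf2 target list and of the extracellular matrix list minus the mean of all genes tested (y axes), by genotype and age (x axis), 1 point per library with group mean and SD. The Nrf2 list lies at 1.24 to 1.40 in knockout and at 1.44 to 1.58 in wild-type libraries at 15 months, and wild-type replicate 1 at 2 months has the highest extracellular matrix level, 1.92.

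The other 9 lists called for the mean over both ages were higher for mitochondrially encoded mRNAs (median 0.26), fatty acid oxidation (0.12), sarcomere (0.11), cell cycle (0.22) and endothelial markers (0.26), and lower for cardiac stress genes (−0.14), inflammation (−0.12), macrophage markers (−0.15) and atrial markers (−0.76). Their adjusted p-values with an estimated correlation were between 0.568 and 0.799. Without wild-type replicate 1 at 2 months the camera adjusted p was 0.957 for atrial markers, 0.752 for inflammation, 0.154 for macrophage markers and 0.0665 for the sarcomere. Other libraries also ended calls: for inflammation, knockout replicate 2 at 2 months (0.301) and at 15 months wild-type replicates 1 (0.230), 3 (0.0586) and 4 (0.0743) and knockout replicate 1 (0.190). For macrophage markers these were knockout replicate 2 at 2 months (0.180), and wild-type replicate 4 (0.209) and knockout replicate 1 (0.103) at 15 months. For the sarcomere they were knockout replicate 2 at 2 months (0.113) and wild-type replicate 4 at 15 months (0.0562), for cardiac stress genes wild-type replicate 3 (0.231) and knockout replicate 1 (0.0685) at 2 months and wild-type replicate 1 at 15 months (0.107), and for mitochondrially encoded mRNAs knockout replicate 1 at 15 months (0.0557). Adjusted over the list alone, Mgat4b (0.50), Cidea (0.38) and Cnn1 (−1.66; −0.91 without wild-type replicate 1 at 2 months) passed in their lists.

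No gene passed the test of a difference between the knockout effects at 15 and 2 months (0 genes by the edgeR quasi-likelihood test, DESeq2 and limma voom, 577 genes at an unadjusted p below 0.05). For Sqstm1 the difference was 0.07 (SE 0.37, edgeR quasi-likelihood unadjusted p = 0.857). The fixed genes gave Hmox1 1.06 (SE 0.50), Nfe2l2 0.32, Gclc 0.29, Gclm 0.21, Nqo1 −0.10, Txnrd1 −0.21, Keap1 −0.26, Nppa −0.94, Nppb −0.89, Myh7 −0.32, Nbr1 −0.08 and Map1lc3b −0.10, and the signs of Nqo1, Nppa, Myh7, Nbr1 and Map1lc3b turned in other settings. For the Nrf2 target list the camera adjusted p of the difference was 0.704. Across the 15528 genes the knockout effects at the 2 ages, which share no library, had a Pearson correlation of 0.0684 and a Spearman correlation of 0.0212, and 51.1% of genes had the same sign. Genes are not independent replicates, so these describe the fold changes only.

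Gene lists of connective tissue and immune cells differed between the ages in their knockout effect, being higher relative to wild type at 15 months than at 2 months. Extracellular matrix had 38 of 38 members above 0 and a median difference of 1.31 (camera with Benjamini-Hochberg adjusted p = 3.27e-19), with Thbs1 at 2.74 (SE 0.85) and Thbs4 at 1.67 (SE 0.55; 0.95 without wild-type replicate 1 at 2 months). Fibroblast markers had 18 of 18 above 0 and 0.99 (2.49e-15), with Mfap5 at 1.10 (SE 0.25) and Smoc2 at 0.83 (SE 0.25) passing adjusted over the list alone, inflammation 23 of 25 above 0 and 0.89 (1.01e-06), and macrophage markers 20 of 21 above 0 and 0.48 (1.01e-06). With an estimated correlation these adjusted p-values were 0.263, 0.231, 0.281 and 0.231. The sarcomere list had 20 of 20 members below 0 and a median of −0.28 (0.000405; adjusted p = 0.231 with an estimated correlation), and the 3 measured genes of the skeletal muscle, lung, thymus and liver list, all muscle genes, a median of −0.68 (0.00644; adjusted p = 0.231 with an estimated correlation). These 6 calls held without any 1 library with the preset correlation. Without wild-type replicate 1 at 2 months the difference in the extracellular matrix list mean, relative to all genes, went from 1.03 to 0.54. Its exact permutation p was 0.119 with all libraries and 0.226 without that one. Among neighbours of Sqstm1, Gfpt2 at 1.78 (SE 0.44) passed adjusted over the list alone.

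The other 6 lists called for the difference rested on single libraries, and their adjusted p-values with an estimated correlation were between 0.578 and 0.717. Immediate early genes had a median of 0.63 (camera adjusted p = 0.000441), and 0.183 and 0.0572 without wild-type replicates 1 and 3 at 2 months. Cell cycle genes had a median of 0.43 (0.00475), and the adjusted p was 0.0968 without wild-type replicate 3 at 2 months and 0.120 without wild-type replicate 2 at 15 months. Nuclear-encoded oxidative phosphorylation had a median of −0.17 (0.000921), with 0.291 without wild-type replicate 1 at 2 months and 0.0890 without knockout replicate 3 at 15 months. The proteasome had a median of −0.12 (0.0289; 0.255 with the length slope as a covariate), with 0.758 and 0.232 without wild-type replicate 1 and knockout replicate 3 at 2 months, and 0.261 and 0.273 without wild-type replicate 2 and knockout replicate 3 at 15 months. Calcium handling had a median of −0.14 and a mean of 0.31, which differ in sign (0.0388, called lower). Its adjusted p was 0.161 and 0.236 without replicate 2 of wild type and of knockout at 2 months, and 0.235, 0.247 and 0.0562 without wild-type replicate 1 and knockout replicates 1 and 3 at 15 months. Glycolysis had a median of −0.15 (0.0289), with 0.260, 0.205 and 0.120 without wild-type replicate 2 and knockout replicates 2 and 3 at 2 months, and 0.112, 0.0702, 0.274 and 0.0562 without wild-type replicates 1 and 3 and knockout replicates 1 and 3 at 15 months.

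With age in wild-type hearts 161 genes changed, 95 higher and 66 lower at 15 months, of which 148 were protein coding. Ano5, an anoctamin of muscle, rose by a log2 fold change of 4.23 (SE 0.37), from 0.782 ± 0.257 to 14.7 ± 1.86 CPM (SD, n = 3 and 4). The amylase gene Amy1 rose by 3.19 (SE 0.19), from 2.78 ± 0.754 to 25.2 ± 2.93 CPM. The cadherin Cdh4 rose by 3.06, the phosphodiesterase Pde11a by 3.20, Lgi2 by 3.02, the potassium channel Kcnc1 by 3.37 and the immunoglobulin gene Ighg2c by 2.88. The amino acid transporter Slc38a1 fell by 2.92 (SE 0.23), from 20.6 ± 5.45 to 2.73 ± 0.524 CPM. Also lower were Ddc and Dbh, enzymes of catecholamine synthesis (−3.01 and −2.45), Adamtsl2 (−2.46), the CGRP receptor subunit Ramp1 (−2.35), Tmem35a (−2.11), the fibrillin Fbn2 (−2.04) and the long non-coding RNA Eprn (−2.67). The highest adjusted p among these genes was 0.0430 (Fbn2, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment).

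Several genes of the fixed lists also changed with age in wild type. The autophagy receptor Optn rose by 0.71 and the clock repressor Bhlhe41 by 1.09, while the matrix protein gene Sparc (−0.73), the microfibril gene Mfap5 (−1.18), the immediate early gene Btg2 (−1.57) and the sarcomere gene Myoz2 (−1.12) fell. Gsta2 rose from 2 counts to 92 counts over the libraries of the groups, a ratio of 28.2 with an exact 95% counting interval of 7.59 to 237. None of the 12 fixed genes passed (lowest adjusted p = 0.103, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), with Myh7 at 1.93 (SE 0.76), Nppa at −2.18 (SE 1.06), Nppb at −1.499, Nqo1 at 0.47, Txnrd1 at 0.46, Nbr1 at 0.68, Map1lc3b at −0.44, Hmox1 at −0.46, Nfe2l2 at −0.20, Keap1 at 0.16, Gclm at 0.08 and Gclc at 0.0036, and the signs of Hmox1, Gclc and Gclm turned in other settings. Of the 23 genes past the threshold named for this comparison by the rule, 11 stayed past it when each library was left out in turn, among them Ano5, Amy1, Pde11a, Cdh4, Lgi2, Ddc, Slc38a1, Adamtsl2, Dbh and Mfap5.

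Camera called 12 lists with age in wild type, all with an adjusted p of 0.645 or 0.787 with an estimated correlation. Nuclear-encoded oxidative phosphorylation had 36 of 44 members below 0 and a median of −0.46 (camera with Benjamini-Hochberg adjusted p = 0.000429), with 5 lower adjusted over the list alone. Immediate early genes had 22 of 23 members below 0 and a median of −1.01 (0.000625; 8 lower and 1 higher adjusted over the list alone), and the call ended without wild-type replicate 1 at 2 months (0.103), the library with Fos at 30.2 CPM. Extracellular matrix (−0.60, adjusted p 0.00542), fibroblast (−0.52, 0.00573) and macrophage markers (−0.34, 0.00573) lay lower, and without that library their camera adjusted p was 0.908, 0.692 and 0.0948, while without wild-type replicate 2 at 15 months it was 0.147, 0.108 and 0.0905. Other antioxidant enzymes (−0.32, 0.00787) and the proteasome (−0.32, 0.00573, and 0.128 without wild-type replicate 3 at 2 months) lay lower too. Nrf2 targets (0.15, 0.0250; 6 higher and 1 lower adjusted over the list alone), glycolysis (0.25, 0.0156), fatty acid oxidation (0.28, 0.0156), calcium handling (0.24, 0.0191) and the sarcomere (0.32, 0.0366; 7 higher and 1 lower adjusted over the list alone) lay higher. Without wild-type replicate 1 at 2 months these 5 had camera adjusted p-values of 0.0948, 0.0847, 0.103, 0.0847 and 0.230, and 3 lists were called in place of 12. With the length slope as a covariate, added after the data were seen, the directions of oxidative phosphorylation and the proteasome turned (camera adjusted p = 0.871 for both), and the calls of other antioxidant enzymes (0.415), the sarcomere (0.101), calcium handling (0.217), fatty acid oxidation (0.729) and glycolysis (0.329) ended. The length slope differed between the ages, so these moves do not separate an effect of length from one of age. Libraries that also ended a call were wild-type replicate 2 at 2 months (Nrf2 targets 0.0524, glycolysis 0.0791) and at 15 months replicate 1 (calcium handling 0.0640, sarcomere 0.0682), replicate 2 (Nrf2 targets 0.0834) and replicate 3 (fatty acid oxidation 0.0730, sarcomere 0.0574).

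The number of genes called with age in wild type depended on single libraries. It was 511 without wild-type replicate 1 at 2 months, with 202 higher and 309 lower, 38 without replicate 2 and 63 without replicate 3, and at 15 months it was 49 without replicate 1 (38 higher and 11 lower), 80 without replicate 3 (68 higher and 12 lower) and 82 without replicate 4. DESeq2 called 1067 genes, 534 higher and 533 lower, of which 160 were among the 161. In the simulated comparison DESeq2 made 25 false calls where edgeR made 2, and it recovered more seeded genes. Its shares were 20.9%, 62.7% and 98.5% at 1.5-fold, 2-fold and 4-fold, against 5.97%, 44.8% and 92.4% by edgeR.

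With age in knockout hearts 349 genes changed, 166 higher and 183 lower at 15 months, of which 307 were protein coding. Amy1 rose by 3.96 (SE 0.20), from 1.43 ± 0.0664 to 22.3 ± 1.94 CPM (SD, n = 3 and 4), and Ano5 by 4.12 (SE 0.37), from 0.824 ± 0.562 to 14.4 ± 3.69 CPM. The cadherins Cdh22 and Cdh4 rose by 4.18 and 3.85, Ighg2c by 3.28, and the potassium channel Kcnk1 by 5.65 (SE 0.70; 9.40 without knockout replicate 1 at 2 months) from a mean of 0.0674 CPM at 2 months, a level near 0 that sets the size of this change. Tenm2 rose by 3.59 from 0.192 to 2.37 CPM, both low levels. Slc38a1 fell by 3.01 (SE 0.23), from 27.2 ± 2.91 to 3.35 ± 0.857 CPM. Also lower were Ddc (−2.90), Eprn (−3.25), Hsbp1l1 (−2.64), Ramp1 (−2.29), the RNA component Rmrp (−2.16), the potassium channel subunit Kcne1 (−2.005) and Tmem35a (−1.99). The highest adjusted p among these genes was 0.0392 (Tenm2, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment).

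Members of the fixed lists also changed with age in knockout hearts. The methionine sulfoxide reductase Msrb1 (−1.15), the peroxiredoxin Prdx4 (−0.997), the glutathione peroxidase Gpx7 (−0.68) and thioredoxin Txn1 (−0.92) fell, and the Nrf2 target Aox1 rose by 1.05. The cytochrome c1 gene Cyc1 (−0.79), the proteasome subunit gene Psmb7 (−0.68), the glycolytic genes Pgk1 and Eno3 (−0.55 and −0.71), the channel genes Hcn2 and Kcnip2 (−0.68 and −0.88), Myoz2 (−1.17) and the smooth muscle actin Acta2 (−1.31) fell. Pfkfb1 rose by 1.503, Fhl1 by 1.03, the lysosomal gene Cln3 by 0.82, and the clock genes Bhlhe41 and Hlf by 1.14 and 0.78. The p53 targets Phlda3 and Eda2r fell (−1.43 and −1.10), and so did the fast skeletal myosin light chain Mylpf (−2.999). None of the 12 fixed genes passed (lowest adjusted p = 0.105, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), with Nppa at −3.12 (SE 1.09), Nppb at −2.39, Myh7 at 1.61, Hmox1 at 0.60, Nbr1 at 0.60, Map1lc3b at −0.54, Nqo1 at 0.37, Gclc at 0.29, Gclm at 0.29, Txnrd1 at 0.25, Nfe2l2 at 0.12 and Keap1 at −0.10, and the signs of Nfe2l2, Txnrd1 and Nbr1 turned in other settings. Of the 37 genes past the threshold named for this comparison, 12 stayed past it when each library was left out in turn, among them Kcnk1, Cdh22, Ano5, Amy1, Cdh4, Eprn, Slc38a1, Ddc, Hsbp1l1, Kcne1 and Phlda3.

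Camera called 10 lists with age in knockout hearts. Nuclear-encoded oxidative phosphorylation had 39 of 44 members below 0 and a median of −0.65, with 1 lower over all genes and 29 adjusted over the list alone (camera with Benjamini-Hochberg adjusted p = 3.48e-10; adjusted p = 0.567 with an estimated correlation and 0.0338 by fry). Other antioxidant enzymes had a median of −0.41, with 3 lower over all genes and 13 lower and 1 higher adjusted over the list alone (0.000473; 0.567 with an estimated correlation, 0.0177 by fry). The proteasome had a median of −0.43, with 1 lower over all genes and 14 adjusted over the list alone (1.03e-05; 0.844 with an estimated correlation). Nrf2 targets had a median of 0.25, with 1 higher and 1 lower over all genes and 9 higher and 3 lower adjusted over the list alone (0.0231; 0.513 with an estimated correlation, 0.0177 by fry, and 0.121 without knockout replicate 2 at 2 months). Extracellular matrix (median 0.74, camera adjusted p 0.00249), inflammation (0.61, 0.00249), endothelial markers (0.53, 0.00646), fibroblast markers (0.47, 0.0136) and clock genes (0.44, 0.0303) lay higher, and the 3 measured genes of the skeletal muscle, lung, thymus and liver list, all muscle genes, lower (−1.40, 0.00247). With an estimated correlation these adjusted p-values were 0.874, 0.862, 0.862, 0.874, 0.862 and 0.149. Without knockout replicate 3 at 15 months the camera adjusted p was 0.0777 for extracellular matrix and for endothelial markers. With the length slope as a covariate the directions of extracellular matrix, fibroblast and endothelial markers turned (camera adjusted p = 0.000819, 0.542 and 0.551), and the antioxidant, proteasome and inflammation calls ended (0.179, 0.424 and 0.785). Since the slope differed with age in knockout hearts too, these moves do not separate length from age. Inflammation lost its call without knockout replicate 2 at 2 months (0.0502), and the clock list without knockout replicate 1 (0.152) or 2 (0.0636) at 2 months, or 1 (0.0782) or 2 (0.0530) at 15 months.

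The count of genes called with age in knockout hearts moved with each library. It was 3523 without knockout replicate 1 at 15 months, the library with a length slope of −0.067, and then held 348 of the 349 genes. It was 116, 89 and 94 without replicates 2, 3 and 4 at 15 months, and 49, 84 and 69 without replicates 1, 2 and 3 at 2 months. With the length slope as a covariate, which takes up part of the age difference, 56 genes were called, 38 of them among the 349. Limma voom called 485 genes, 151 higher and 334 lower. Genes higher at 15 months had a median exon length of 5948 bases in knockout and 6856 in wild type, and genes lower at 15 months 1971 and 3099, against 4113 for all genes tested.

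The changes with age in both genotypes, which rest on separate libraries, overlapped. Of the genes called, 57 were higher in both genotypes, where independent lists of these sizes share 1.02, and 24 were lower in both, where independent lists share 0.778. Of the 429 genes called in either genotype, 422 had the same direction in both, and 0 were called in opposite directions. Across all genes the Pearson correlation of the log2 fold changes was 0.614, and across the called genes 0.841. No gene passed the test of a difference between genotypes in the change with age, which is the same contrast as the difference between the knockout effects.

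**Figure D4:**
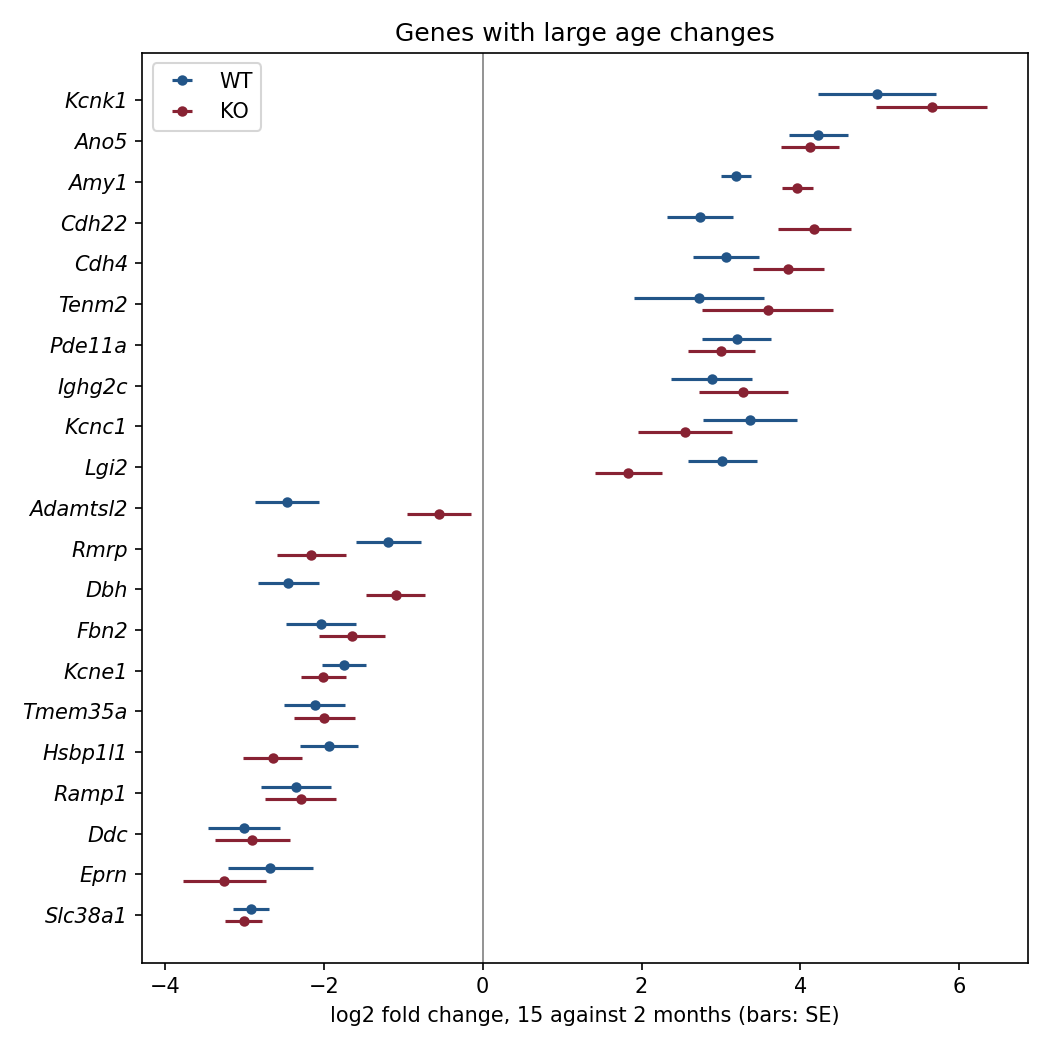
Log2 fold change between 15 and 2 months (x axis, bars are SE) in wild-type and knockout hearts for the genes with large changes named for either genotype (y axis). Ano5 and Amy1 lie at 4.23 and 3.19 in wild type and 4.12 and 3.96 in knockout, and Slc38a1 at −2.92 and −3.01.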

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

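The tests that leave out wild-type replicate 1 at 2 months were chosen as tests of the extracellular matrix pattern after its result was seen, and the tests that reassign genotypes were chosen before. Library measures, Sqstm1 and the fixed genes were checked by Dixon's test for a library far from the others, in each of the 2 groups of 4 libraries. Of these 40 checks 2 found one, where chance gives about 1 in 20. The checks share the same libraries, so they are not independent. Sqstm1 in knockout replicate 2 at 15 months was at 37.0 CPM against 14.6 to 17.6 CPM in the other 3, a gap of 0.867 of the range. Map1lc3b in wild-type replicate 2 at 15 months had a gap of 0.942 of the range.

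The knockout effect differed between the ages in 12 gene lists by camera with Benjamini-Hochberg adjustment, and in 0 of them with an estimated correlation. The adjusted p-values were 3.27e-19 for extracellular matrix, 2.49e-15 for fibroblast markers, 1.01e-06 for inflammation and for macrophage markers, 0.000405 for the sarcomere, 0.000441 for immediate early genes, 0.000921 for nuclear-encoded oxidative phosphorylation, 0.00475 for cell cycle genes, 0.00644 for the skeletal muscle, lung, thymus and liver list (only muscle genes measured), 0.0289 for the proteasome and for glycolysis, and 0.0388 for calcium handling. Of 100 splits of the samples, the real one included, 53 called as many lists (real 12, highest other 21), so chance cannot be excluded for the number of lists.

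The extracellular matrix list lay lower in knockout hearts at 2 months and higher at 15 months. At 2 months the call ended without wild-type replicate 1, the library with atrial transcripts (limma camera adjusted p = 0.163), so tissue of the atrium in that library may account for it, which stays open. The same library held Adipoq, a fat cell gene, at 6.75 CPM, against 0.0404 to 0.253 CPM in the other 2-month libraries. Other tissue was not tested. Among 15-month libraries the list level was −0.193 to 0.881 where Myl7 was 15.0 to 58.1 CPM, and 0.823 to 1.66 in the rest. Atrial transcripts thus did not go with high matrix levels there, at far lower Myl7 than the 638 CPM of wild-type replicate 1. At 15 months 15 of 35 splits, the real one included here and below, gave a mean list shift as far from 0 (real 0.40, highest other 0.82), and for the difference between ages 83 of 700 assignments of genotype did (real 1.03, highest other 1.45, exact permutation p = 0.119), so chance cannot be excluded for either. Without wild-type replicate 1 the knockout effect at 2 months went from −0.63 to −0.13 and the difference from 1.03 to 0.54, which stayed called (limma camera adjusted p = 3.15e-07 with the preset correlation; with all libraries 0.263 with an estimated one) but was reached in 158 of 700 assignments (exact permutation p = 0.226), so that library stays open as its source. An effect of Sqstm1 loss on connective tissue that turns with age stays open.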

How the results depend on the processing

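The length slope, the atrial score and 2 surrogate variables were added as covariates after the data were seen, and the other alternatives were planned. Sqstm1 stayed lower and past the threshold in all settings run, with exact p = 0.1 and 0.0286, and its log2 fold change was −3.43 to −3.23 at 2 months and −3.64 to −3.09 at 15 months without 1 library. RLE size factors and limma voom moved no count of genes by over 1.5 times. The cause was not tested for any change below, except that leaving out a library leaves fewer samples. With 3 or 4 hearts per group, changes of 1.5-fold were mostly below detection, and no median of all genes moved by more than 0.03.

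Between genotypes at 2 months 1 gene became 3 with no filter, 2 with a stricter filter, 5 with DESeq2, 4 with the length slope, 3 with 2 surrogate variables and 2 at an adjusted p below 0.1, and 1 to 1 without 1 library. At 15 months it became 6 with DESeq2 and 2 with only the groups compared, and 1 to 3 without 1 library. For the mean it became 3 with DESeq2 and 2 with surrogate variables, and 1 to 1 without 1 library. Genes called with age in wild type (161) were 1067 with DESeq2, 86 with only the groups compared, 84 with the atrial score, 304 with surrogate variables, 100 at 2-fold or more, 706 at an adjusted p below 0.1 and 38 to 511 without 1 library. In knockout (349) they were 1600, 134, 174, 139, 226, 1616 and 49 to 3523 in the same settings, and 56 with the length slope. The difference gave 1 gene with surrogate variables and 0 to 1 without 1 library. DESeq2 kept 160 of the 161 and 344 of the 349. The Pearson correlation of the knockout effects at the 2 ages was 0.0247 with no filter and 0.0189 to 0.171 without 1 library; it was not run over only the genes changed at either age, which hold 1 gene.

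Lists called fell to 0 in all 6 contrasts with an estimated correlation, and with fry to 0 in 5 and 4 with age in knockout. Of 64 single list results, 22 lost their call and kept their direction with surrogate variables, 11 with the length slope and 5 with the atrial score, and a further 2, 5 and 1 turned in direction. Surrogate variables left 6 for the mean and 5 with age in wild type. Without 1 library the number was 2 to 17 at 2 months, 6 to 14 at 15 months, 7 to 15 for the mean, 3 to 14 and 7 to 12 with age in wild type and knockout, and 9 to 16 for the difference.

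Replicate numbers did not pair the libraries throughout: same-numbered correlations were −0.127, −0.176 and 0.465 at 2 months and −0.555, −0.379, 0.237 and 0.349 at 15 months, and across ages 0.284, 0.443 and −0.185 in wild type and 0.379, 0.267 and −0.0291 in knockout. The best correlations of the same wild-type libraries with another number were 0.360, 0.432 and −0.246 at 2 months and 0.480, 0.696, 0.585 and 0.0309 at 15 months. Replicate 3 at 2 months and replicate 4 at 15 months thus correlated best with their own number, and the others did not. With a replicate block 1, 1, 1 and 0 genes were called between genotypes at 2 months, at 15 months, for the mean and for the difference, 55 and 70 with age in wild type and knockout, and 10, 12, 10, 12, 10 and 9 lists at 2 months, at 15 months, for the mean, with age in wild type, in knockout and for the difference. The block gave Sqstm1 −3.30 and −3.34. It ended the calls of the sarcomere with age in wild type (0.0506) and, for the difference, of the proteasome (0.0517), calcium handling (0.0658) and glycolysis (0.0658).

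Signs that turned, as log2 fold changes of genes that did not pass, were these. At 2 months Nfe2l2 was −0.021 with surrogate variables and −0.22 to 0.34 without 1 library, Gclm −0.056 with the atrial score, −0.15 with surrogate variables and −0.068 to 0.16, Nppa 0.46 with the atrial score and −0.89 to 0.30, Nppb 0.045 with voom and −0.75 to 0.26, and Map1lc3b −0.18 to 0.053. At 15 months Gclc was −0.017 with surrogate variables and −0.027 to 0.10, Nppa −2.07 to 0.056, Myh7 −0.061 to 0.95 and Map1lc3b −0.28 to 0.012. For the mean Keap1 was −0.059 to 0.016, Hmox1 0.011 with the block and −0.13 to 0.23, Gclm −0.017 with surrogate variables and Nppa 0.0071 with the atrial score.

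With age in wild type Hmox1 was −0.70 to 0.020 without 1 library, Gclm −0.10 with the length slope, −0.077 with surrogate variables and −0.00027 to 0.23, and Gclc −0.015 with a stricter filter, −0.0063 with voom, −0.00046 with only the groups compared, −0.020 with the block, −0.0070 without mitochondrial genes, −0.11 with the length slope, −0.098 with surrogate variables and −0.057 to 0.070. With age in knockout Nfe2l2 was −0.23 with the length slope, −0.12 with surrogate variables and −0.053 to 0.49, Txnrd1 −0.0014 with the length slope and Nbr1 −0.20 and −0.051 with the length slope and surrogate variables. For the difference Nqo1 was 0.077 with surrogate variables and −0.43 to 0.063, Nppa 0.071 with voom and −1.79 to 0.60, Myh7 −1.16 to 0.43, Nbr1 −0.26 to 0.089, and Map1lc3b 0.013 with the length slope, 0.044 with surrogate variables and −0.22 to 0.070.

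Lists whose direction turned had these adjusted camera p-values: atrial markers 8.80e-07 to 0.401 at 2 months without 1 library and 0.862 for the mean with the atrial score; with age in wild type the proteasome 0.871 and oxidative phosphorylation 0.871 with the length slope; with age in knockout extracellular matrix 0.000819 and 0.000453 and fibroblast markers 0.542 and 0.152 with the length slope and surrogate variables, and endothelial markers 0.551 with the length slope; and Nrf2 targets 0.324 to 0.991 for the difference without 1 library.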

Other observations

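In the part on Nrf2 targets, the tests with the length slope as a covariate and without wild-type replicate 1 were chosen after the result was seen; in the part on age, the length slope as a covariate was chosen after the data were seen, the genes for the test of time of collection were chosen after its result on all called genes was seen, and the tests of wrong labels were prompted by the splits of the samples.

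Clock genes differed with age in both genotypes, with 6 of 19 higher and 3 lower in each, adjusted over the list alone. The clock transcript Ciart was at 20.2 and 16.3 CPM in replicate 3 of both genotypes at 2 months, above all 15-month libraries (7.07 to 13.6 CPM), and at 0.657 to 1.20 CPM in the other 2-month libraries. In the senescence and p53 list 4 members were higher and 6 lower with age in knockout hearts, adjusted over the list alone.

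The Nrf2 target list lay lower in knockout hearts averaged over both ages. Of 700 assignments of genotype within ages, the real one included, 4 gave a mean shift as far from 0 (real −0.149, highest other 0.163, exact permutation p = 0.00571). That is rare for the list taken alone. Chance cannot be excluded after adjustment over the 34 lists (exact permutation test with Benjamini-Hochberg adjusted p = 0.194). The mean counts all 33 members equally, so Gsta1 and Gsta2, similar copies at low levels with large falls at 15 months, can weigh heavily in it. It was not computed without them. With the preset correlation, though not with an estimated one (adjusted p = 0.0724) or by fry (adjusted p = 0.0776), the list stayed called with the length slope as a covariate (limma camera adjusted p = 2.96e-05) and without wild-type replicate 1 at 2 months (limma camera adjusted p = 0.00253), with exact permutation p = 0.00286 and 0.00857 for its mean shift, which argues against a gene length trend or the atrial tissue of that library as the whole cause. At 15 months Myl7 was at 39.7, 15.0 and 26.9 CPM in wild-type replicates 1, 2 and 4 and at 58.1 CPM in knockout replicate 1. These libraries were kept, so that test cannot speak on atrial tissue at 15 months, which stays open. A candidate explanation is that loss of Sqstm1 in cardiac muscle lowers Nrf2 target transcripts, and 15 of 33 members lay below 0 at both ages, a number reached in 76 of 1400 assignments (highest other 22). That count does not separate the hypothesis from chance, so it stays open.

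The genes called with age lay apart by length, longer genes being higher at 15 months, and 71.4% of them in wild type and 77.9% in knockout moved in the direction that length predicts. The difference in length slope gave a median of 6.62% and 13.3% of the called change, so a linear trend of this slope gives little of its size. The called genes were picked for their changes, so a low share was likely beforehand. It does not argue against length as a cause of the calls. With the length slope as a covariate 60 of the 161 and 38 of the 349 genes kept their call. The slope itself differed with age, with a mean of −0.111 in both genotypes at 2 months, and 0.0609 in wild type and 0.105 in knockout at 15 months. The covariate therefore takes up part of the age difference, and the lost calls cannot tell whether length bears on which genes pass, which stays open. Of 35 splits in each genotype, the real one included, 2 called as many genes, which does not exclude chance. The real counts were 161 in wild type (highest other 723) and 349 in knockout (highest other 4027). Separate libraries shared 57 and 24 genes, where 1.02 and 0.778 are expected if genes are called independently. Single splits called many genes together, and the overlap was not run under reassigned ages, so that expectation cannot weigh against chance. The highest splits, which keep most of the age groups together, point to a structure of the samples: in knockout replicate 1 at 15 months stood with the 2-month libraries, apart from the replicates with the highest length slopes, and in wild type replicate 1 at 2 months and replicate 2 at 15 months changed places. The median share of the age change was 77.9% in knockout replicate 1 at 15 months (quartiles 42.7% and 97.4%). It was 39.4% in wild-type replicate 1 at 2 months (9.41% and 67.6%) and 72.8% in wild-type replicate 2 at 15 months (45.2% and 101%). The medians argue only weakly against wrong labels, since each of these ranges spans 50%. Time of collection was tested with 2-month replicate 3, which has high clock transcripts. Of the change in the 43 and 69 genes called without replicate 3 at 2 months it held a median of 20.2% and 5.02% (upper quartiles 43.3% and 26.5%), though 50% or more in 9 and 8 of them. Its Dbp was at 71.4 CPM in wild type and 83.9 CPM in knockout, below the 85.9 to 127 CPM at 15 months, while its Ciart lay above. Replicate 3 need not share the 15-month time of day, so its low shares do not exclude time of collection. An effect of age, the difference the design names, stays open beside this and a structure of the libraries that differs between the ages.

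For the other counts, splits of the samples were as follows, the real one included in each number. Between genotypes at 2 months the 10 splits are too few for a share under 0.05: 1 split gave as many genes (real 1, highest other 0) and 10 as many lists (real 9, highest other 20). At 15 months 3 of 35 splits called as many genes (real 1, highest other 45) and 15 as many lists (real 10, highest other 16), and for the mean over both ages 6 of 100 called as many genes (real 1, highest other 10) and 69 as many lists (real 10, highest other 19). For the difference between ages the real count of genes is 0 (highest other 6), so 100 of 100 splits call as many by construction and the splits say nothing. With age 14 of 35 splits called as many lists in wild type (real 12, highest other 16) and 21 of 35 in knockout (real 10, highest other 20). The 1 gene called between genotypes at 15 months and for the mean was Sqstm1, the targeted gene. A count of 1 that other splits reach with other genes does not bear on that gene. Sqstm1 was lower in every knockout library than in any wild-type library (exact permutation p = 0.0286 at 15 months), which argues against chance for it. Chance cannot be excluded for the counts of lists with 35 or 100 splits, and the splits with 45 and 10 genes point to a structure of the samples.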
